A study of Mus musculus with 6 samples.

How the data were processed

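Total RNA from day 3 embryoid bodies was profiled on 6 Illumina mouse bead arrays, all on 1 slide, with 3 arrays labelled wild type and 3 labelled endoglin knockout. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with DNase treatment, and amplified to biotinylated cRNA. The labels give the strain C57BL/6 for all samples, while the series names E14 ES cells as the control, a line of another strain background; this was not resolved here. The values used were the authors' deposited intensities, 1 per probe and array, on a linear scale. How the authors normalized them is not given in the sources used here. The 6 columns had the same highest value (32123) and nearly the same median, as after quantile normalization, and no background subtraction was visible, with a background peak near 38.8 on each array.

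A second deposited table holds unnormalized signals and detection p-values, but its 12 value columns carry running numbers that match no sample label, and they were not used. The planned background correction from detection p-values (neqc) and the planned filter on detection p-values could not therefore be run. The fallback fixed beforehand was normexp (offset 50) followed by quantile normalization. The intensities were corrected with normexp (offset 50) and taken to log2 in limma 3.58.1 under R 4.3.3, but the quantile step of that fallback was left out, because the columns already shared nearly one distribution; it was run as an alternative. The offset shrinks the differences of dim probes, so fold changes on this scale understate changes of dim genes. A probe was kept when it exceeded, on at least 3 of the 6 arrays, the 95th percentile of a normal background centred on the array's most frequent intensity, with the SD taken from the values below it. This limit was 46.3 to 46.4 per array, it replaced the detection p-value, and it was set after the intensity distributions were seen and before any test between the labels. Of 46632 probes, 22250 were kept.

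Probes were named from the platform annotation, which gives 1 gene for 29976 probes and several for 10. A symbol column of the second deposited table, matched to current or older symbols of the RefSeq gene table (assembly GRCm38.p6), named 5144 more probes of genes that the platform annotation does not cover. The remaining 11502 probes were not named here. Of the 21477 named genes, 21432 were found in the RefSeq table. Each gene was represented by its probe with the highest mean over all 6 arrays, which left 16619 features, 12936 of them named genes.

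The labels were compared with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) over all 6 arrays without covariates. The 26 gene lists were fixed before the data were examined. They cover naive pluripotency, primed epiblast, primitive streak and mesendoderm, haematopoietic and haemangioblast, endothelial, cardiac and lateral plate mesoderm, paraxial mesoderm, definitive and extraembryonic endoderm, neural ectoderm, trophoblast, germ cells, BMP, Nodal and TGF-beta, and Wnt targets, TGF-beta family components, Notch, Hox, cell cycle, p53, hypoxia, stress response, imprinted, feeder fibroblast, matrix and adhesion, and Y-linked genes. Several lists share members. They were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives. The naming rule was also fixed: Eng and Xist; the 12 largest changes per direction among called genes whose labels do not overlap; and for each list up to 4 called members or, where none pass, the 2 with the smallest p. With fewer than 5 genes called in a direction, the 5 with the smallest p there were given as values, leaving out clone and locus names. For 2 lists, 1 member that the rule names is not reported here. Eng was additionally tested with an exact permutation test over 20 groupings.

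The steps were tested on simulated data with the measured means and spread: of 67 genes changed 2-fold in the labelled comparison, 94% were recovered, with 4 false calls among 16619 features, and all 10 simulated lists of 15 genes raised 2-fold were called with 0 false calls among 10 unchanged lists. The simulated noise was independent between genes, unlike real genes of one list, and it held no array clusters. The simulated changes were set on the corrected log2 scale, where the offset makes a 2-fold change in the signal of a dim gene smaller. Similarity of arrays was measured by the number of genes at least 2-fold apart and by correlation across genes. No 2 arrays held identical data. Alternatives covered the background correction, normalization, filter, probe choice, variance model, replicate block, set test, threshold and each array left out. Added after the data were seen were subtraction of the background peak (offset 16), cyclic loess, a further quantile step, slide position as a block, and the omission of the 2 arrays that stood apart from their labels.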

Results

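Expression profiles were measured from embryoid bodies, the aggregates in which mouse embryonic stem (ES) cells differentiate in suspension, collected at day 3. Of the 6 Illumina bead arrays, 3 carried RNA labelled as wild type E14 ES cells and 3 carried RNA labelled as endoglin knockout cells. Endoglin, encoded by Eng, is a co-receptor for ligands of the TGF-beta family. The question named by the series was how loss of endoglin changes expression at this stage. The deposited intensities shared a median of 45.1 on all 6 arrays, and between 47.1% and 47.3% of the 46632 probes lay above the background limit of each array. The number of arrays, 3 per label, limits the precision of every value. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays.

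Eng, the targeted gene, on chromosome 2, did not separate the labels. Of its 2 probes, 1 lay above background on 4 of the 6 arrays, with intensities of 87.0, 90.6 and 44.4 on the arrays labelled wild type replicates 1, 2 and 3, and of 73.5, 45.4 and 48.7 on the arrays labelled knockout replicates 1, 2 and 3. The array labelled knockout replicate 1 therefore lay nearer to wild type replicates 1 and 2, and the array labelled wild type replicate 3 lay at the level of knockout replicates 2 and 3. On the log2 scale Eng averaged 6.56 ± 0.42 (SD, n = 3) under the wild type label and 6.28 ± 0.27 (SD, n = 3) under the knockout label. The difference of -0.28 (SE 0.22) gave an adjusted p of 0.999 in limma (0.000448 to 1.00 over the alternatives) and a two-sided exact permutation p of 0.4, where 0.1 is the smallest that 3 against 3 allows. The second Eng probe was above background on 0 arrays. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so Eng is a limited check of the labels. All directions given here follow the labels as deposited, against which 2 arrays stood apart.

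**Figure D1:**
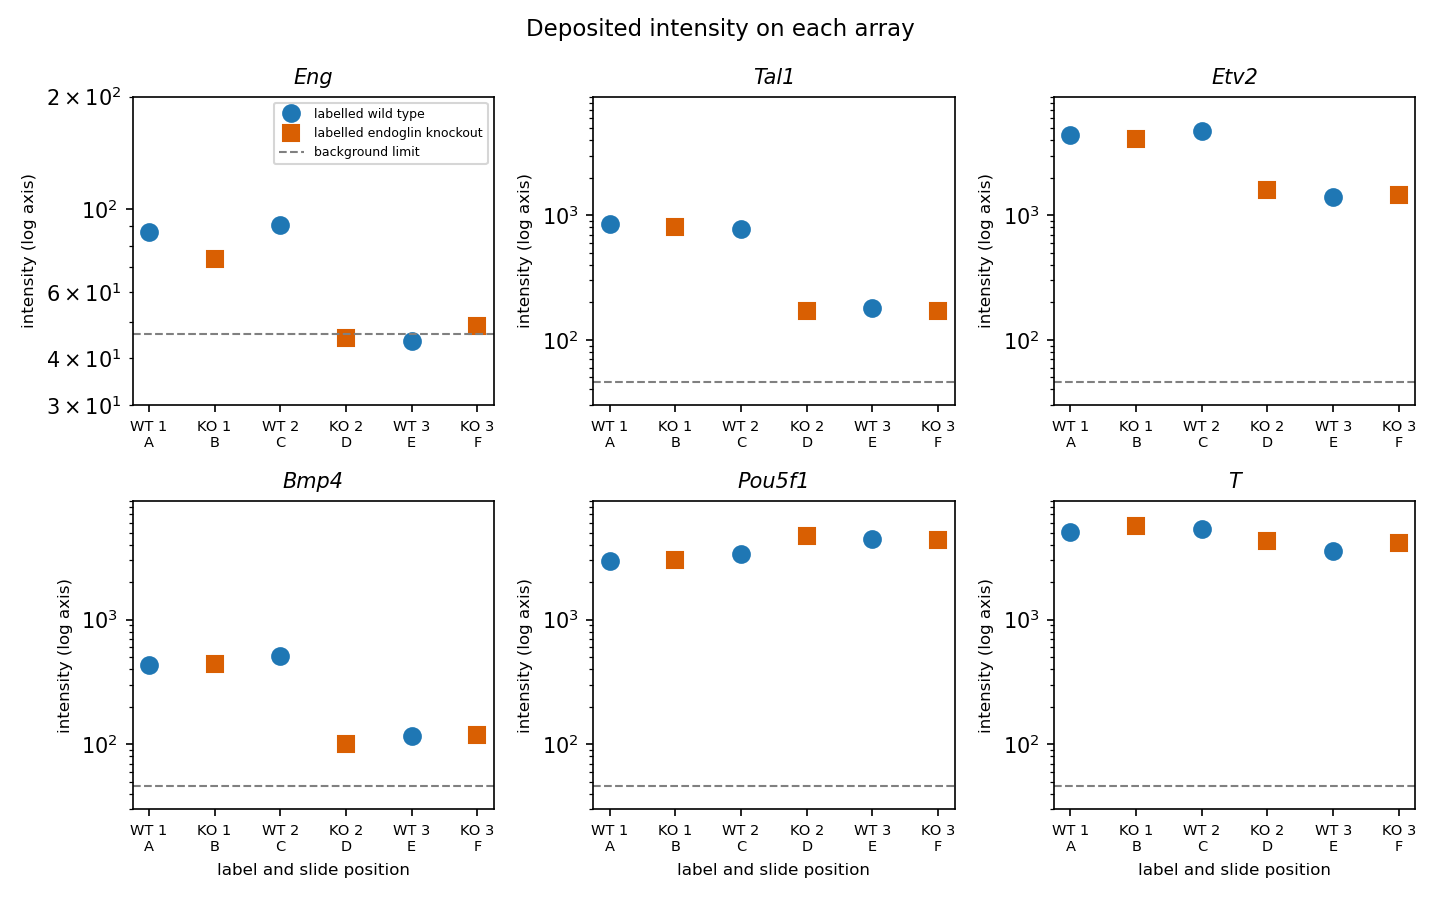
Deposited intensity (log axis, the Eng panel on its own range) of Eng and 5 other genes on each array, ordered by slide position A to F; circles are arrays labelled wild type, squares arrays labelled knockout, and the dashed line is the background limit. For Tal1, the array labelled wild type replicate 3 (181) lay beside knockout replicates 2 and 3 (both 171), and knockout replicate 1 (807) lay between wild type replicates 1 (857) and 2 (771).

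No gene differed between the labels at an adjusted p under 0.05: 0 were higher and 0 lower in the arrays labelled knockout among 16619 genes and unnamed probes tested with limma. At an unadjusted p under 0.05 there were 363, or 2.18%, of which 166 were higher and 197 lower. The smallest adjusted p was 0.999. The 3 arrays of one label all lay on one side of the 3 of the other for 6.99% of the features, where chance gives 10%. In simulated data with the spread within these labels, 94% of 2-fold changes and 59.7% of 1.5-fold changes in randomly chosen genes were recovered. The simulated noise was independent between genes and held no array clusters. The changes were set on the corrected log2 scale, where a 2-fold change in the signal of a dim gene is less than 2-fold. These shares therefore do not apply to changes in the signal of dim genes, such as Eng. Nor do they apply to genes with a wide spread within the labels, such as Tal1 (SE 0.71 on the log2 scale).

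The spread lay within the labels. Wild type replicates 1 and 2 had 2 genes at least 2-fold apart, whereas each of them differed from the array labelled wild type replicate 3 at 104 and 98 genes. Knockout replicates 2 and 3 had 0 such genes between them, while the array labelled knockout replicate 1 differed from them at 84 and 79. Across labels, knockout replicate 1 was 2-fold apart from wild type replicates 1 and 2 at 0 and 2 genes, and wild type replicate 3 was apart from knockout replicates 2 and 3 at 0 genes each. Pairs with the same label correlated across genes at 0.9897 to 0.9969, and pairs with different labels at 0.9893 to 0.9972. Without the arrays labelled knockout replicate 1 and wild type replicate 3, which were left out after the data were seen and because of their values, 1338 genes passed, 627 higher and 711 lower under the knockout label, and the Eng difference was -0.68 (SE 0.08, limma adjusted p = 0.000448). A count obtained by leaving out arrays for their values is not independent evidence of an effect.

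**Figure D2:**
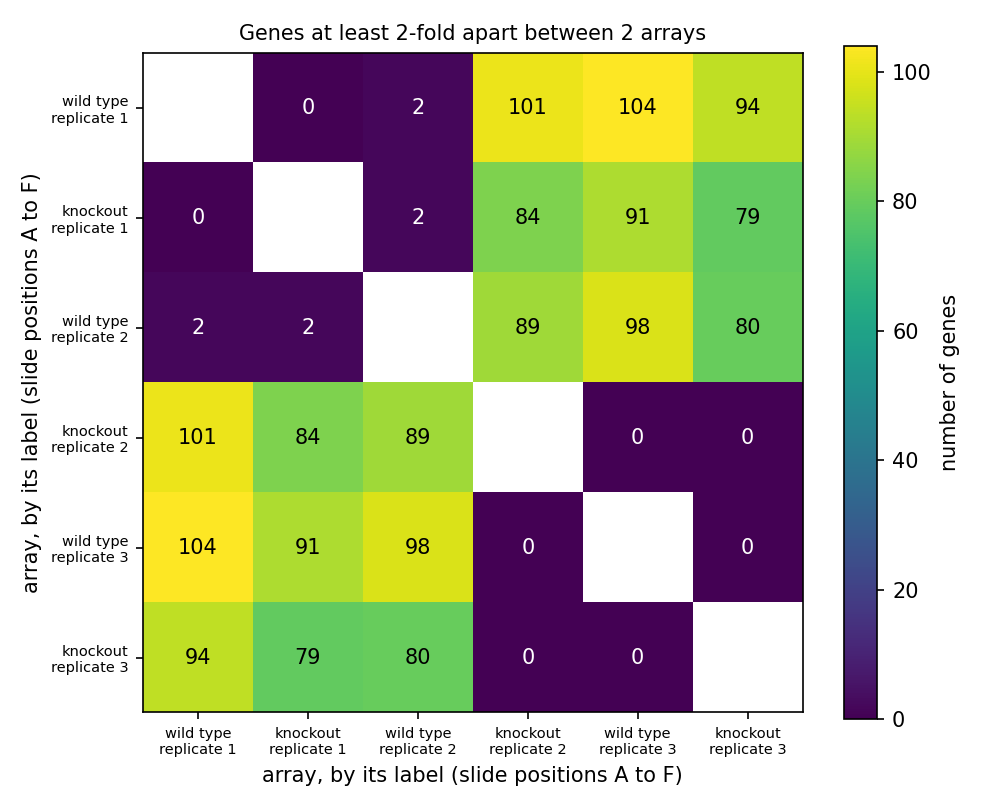
Number of genes at least 2-fold apart for each pair of the 6 arrays, both axes ordered by slide position A to F and named by label. Pairs within positions A to C or within D to F had 0 to 2 such genes, and the other 9 pairs had 79 to 104.

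The genes with the smallest p in each direction differed little and did not pass. Among those with higher values under the knockout label, Supt20 differed by 0.28 (SE 0.07) on the log2 scale, Tubb3, a neuronal beta-tubulin, by 0.29 (SE 0.08), Ndufa12, a subunit of the respiratory chain, by 0.23 (SE 0.07), and Sltm by 0.24 (SE 0.07). Slc17a1 lay below the background limit on all 3 arrays labelled wild type and above it on the 3 labelled knockout, so only a bound can be given, at least 1.02-fold higher, from the means of the corrected log2 values with dim values set to the limit. Lower values under the knockout label were measured for Pank3, a pantothenate kinase of coenzyme A synthesis, at -0.56 (SE 0.14), Zfp68 at -0.28 (SE 0.06), Xrcc2, a DNA repair gene, at -0.26 (SE 0.06), Tmem164 at -0.25 (SE 0.06) and Plod1, a collagen lysyl hydroxylase, at -0.25 (SE 0.06). The limma adjusted p of all 10 was 0.999. Pank3 intensities were 153, 123 and 102 under the wild type label and 91.5, 66.6 and 75.1 under the knockout label.

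Mesoderm genes had the lowest list medians for a lineage, with no single member past the test. In the cardiac and lateral plate list, 0 of 14 measured genes rose and 0 fell, and 12 had lower values under the knockout label, with a median log2 difference of -0.23. Its members with the smallest p were Smarcd3, a chromatin remodelling subunit of heart development, at -0.21 (SE 0.11), and Myl7, an atrial myosin light chain, at -0.68 (SE 0.50). In the paraxial list, 0 of 9 rose or fell and 8 were lower, with a median of -0.19; Msgn1, a presomitic mesoderm factor, differed by -0.17 (SE 0.10) and Mesp2 by -0.19 (SE 0.13). In the reported setting, with all 6 arrays at equal weight, 1 probe per gene and no block, both lists passed camera with a preset correlation (adjusted p = 0.0292 for each), and neither did with an estimated correlation (adjusted p = 0.679 for each). With wild type replicate 1, wild type replicate 2, knockout replicate 2 or knockout replicate 3 left out, 0 lists passed, and with wild type replicate 3 or knockout replicate 1 left out, the same 10 did: both mesoderm lists and the naive pluripotency, haematopoietic, endothelial, BMP target, Wnt target, Notch, Hox and p53 lists. With slide positions A to C against D to F as a block, chosen after the data were seen, neither mesoderm list passed, and the primitive streak and definitive endoderm lists did. Myl7 intensities of 230, 187 and 55.2 under the wild type label, and 165, 51.4 and 49.5 under the knockout label, also spread within the labels. In the primitive streak and mesendoderm list, 9 of 18 genes had higher and 9 lower values and 0 passed (median -0.01, camera direction upward, adjusted p = 0.962). Gsc, an organizer homeobox gene, differed by 0.22 (SE 0.12) and Mesp2 as above, and T (brachyury), chosen after its values were seen, ranged from 3591 to 5612 over the 6 arrays.

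Blood and endothelial genes, the lineages in which endoglin is best known, included no member that passed. Of 18 haematopoietic and haemangioblast genes, 0 rose and 0 fell, and 15 had lower values under the knockout label (median -0.08, camera adjusted p = 0.0788); this list and the endothelial list passed under other settings, among them estimated array weights and the omission of wild type replicate 3 or knockout replicate 1. Spi1, a myeloid transcription factor, differed by -0.16 (SE 0.11) and Kit, the stem cell factor receptor, by 0.12 (SE 0.09). Tal1 and Etv2, which drive haemangioblast formation and were chosen here after their values were seen, varied far more within the labels. Tal1 measured 857, 771 and 181 under the wild type label and 807, 171 and 171 under the knockout label, and Etv2 measured 4382, 4758 and 1392 against 4103, 1593 and 1465. In the endothelial list, 0 of 15 passed and 10 were lower (median -0.11, camera adjusted p = 0.267); Flt4 differed by -0.15 (SE 0.09) and Sox7 by -0.41 (SE 0.29).

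Signalling lists gave no call in camera in the reported setting, but the BMP target, Wnt target and Notch lists passed under other settings, among them estimated array weights and the omission of wild type replicate 3 or knockout replicate 1. The BMP target list had the lowest median of all lists, -0.33, with 10 of 12 members lower, 0 past the test and an adjusted p of 0.0788; Msx2 differed by -0.37 (SE 0.25) and Hey1 by -0.42 (SE 0.37). Of 14 canonical Wnt target genes, 10 were lower and 0 passed (median -0.16, adjusted p = 0.126), with Tcf7 at -0.20 (SE 0.12) and Myc at -0.15 (SE 0.11). Of 12 Notch pathway genes, 9 were lower and 0 passed (median -0.09, adjusted p = 0.0788), with Jag1 at -0.22 (SE 0.09) and Hes1 at -0.12 (SE 0.08). The TGF-beta family ligands, receptors and Smads showed 7 higher and 12 lower of 19 and 0 passed (adjusted p = 0.581), with Smad3 at 0.29 (SE 0.11) and Acvr2b at 0.15 (SE 0.06). Bmp4, a mesoderm-inducing ligand in that list chosen after its values were seen, measured 435, 515 and 116 under the wild type label and 439, 101 and 118 under the knockout label. Among 11 Nodal and TGF-beta targets, 6 were higher, 5 lower and 0 passed (adjusted p = 0.877), with Gsc as above; the median of that list was 0.02 and its mean -0.03.

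Most pluripotency genes had higher values under the knockout label, without a call in the reported setting. The naive list passed under other settings, such as array weights or omission of wild type replicate 3 or knockout replicate 1 (limit as above). Of 19 naive pluripotency genes, 15 were higher and 0 passed (median 0.10, camera adjusted p = 0.0788), with Klf5 at 0.22 (SE 0.09) and Fbxo15 at 0.20 (SE 0.09). The per-array medians of this list were -0.123, -0.139 and 0.175 on wild type replicates 1, 2 and 3. On knockout replicates 1, 2 and 3 they were -0.093, 0.132 and 0.127. The direction was therefore not shared by the arrays of either label, and wild type replicate 3 had the highest median. Pou5f1, which encodes Oct4 and was chosen after its values were seen, measured 2938, 3373 and 4423 under the wild type label and 3005, 4687 and 4352 under the knockout label. Of 10 primed epiblast genes, 7 were higher and 0 passed (adjusted p = 0.581), with Pim2 at 0.22 (SE 0.10) and Fgf5 at 0.33 (SE 0.24).

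No call was made for other lineages in the reported setting. The definitive endoderm list passed only with the slide position block. The Hox list passed under other settings, such as array weights or omission of wild type replicate 3 or knockout replicate 1 (limit as above). In definitive endoderm 0 of 10 passed (adjusted p = 0.521), with Gsc as above and Foxa1 at 0.16 (SE 0.11). In extraembryonic endoderm 0 of 15 passed (adjusted p = 0.885), with Sox7 as above and Foxq1 at 0.09 (SE 0.06). In neural ectoderm 0 of 7 passed (adjusted p = 0.267), with Tubb3 as above and Six3 at 0.06 (SE 0.06). Six3 intensities of 41.0 to 48.7 straddled the background limit, so its difference is poorly measured. In the trophoblast list 0 of 9 passed (adjusted p = 0.789), with Tfap2c at 0.10 (SE 0.10) and Krt7 at 0.30 (SE 0.30). In the germ cell list 0 of 6 passed (adjusted p = 0.789), with Stk31 at 0.12 (SE 0.07) and Ddx4 at -0.08 (SE 0.06). Of 12 Hox genes 9 were lower and 0 passed (adjusted p = 0.0788), with Hoxb1 at -0.19 (SE 0.10).

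Cell state lists gave no call in the reported setting either. The p53 list passed under other settings, such as array weights or omission of wild type replicate 3 or knockout replicate 1 (limit as above). Among 18 cell cycle genes 0 passed (adjusted p = 0.581), with Top2a at -0.18 (SE 0.12) and Aurkb at 0.09 (SE 0.06). Among 11 p53 targets 10 were higher and 0 passed (adjusted p = 0.0788), with Mdm2 at 0.16 (SE 0.08) and Gtse1 at 0.15 (SE 0.09). Hypoxia and glycolysis genes (0 of 14, adjusted p = 0.581) had Ankrd37 at -0.15 (SE 0.09) and Ndrg1 at 0.33 (SE 0.25). Integrated stress response genes (0 of 13, adjusted p = 0.207) had Atf4 at -0.23 (SE 0.10) and Atf3 at -0.19 (SE 0.10). Extracellular matrix and adhesion genes (0 of 17, adjusted p = 0.821) had Lama5 at 0.31 (SE 0.12) and Hspg2 at 0.15 (SE 0.09). Of 19 imprinted genes, 8 were higher, 11 lower and 0 passed (adjusted p = 0.789), with Slc38a4 at -0.41 (SE 0.21) and Rian at 0.19 (SE 0.10).

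Markers of fibroblasts, which are used as feeder cells in ES cell culture, did not pass either: 0 of 10 measured members (camera adjusted p = 0.352), with Acta2 at -0.21 (SE 0.07) and Dcn below the background limit on all 3 arrays labelled wild type, which gives a bound of at least 1.03-fold higher under the knockout label. Of the Y-linked genes, 3 were measured and 0 passed (adjusted p = 0.352), with Kdm5d at -0.07 (SE 0.07) and Uty at -0.06 (SE 0.11). Kdm5d intensities of 40.6 to 49.1 also straddled the background limit. Xist, the RNA that coats the inactive X chromosome, had 2 probes. The brighter ranged from 64.2 to 70.5 and differed by -0.01 (SE 0.06) between the labels, and the dimmer lay below the background limit on all 6 arrays. The median and mean differed in sign for definitive endoderm (0.04 and -0.003), extraembryonic endoderm (0.001 and -0.04) and matrix and adhesion genes (-0.02 and 0.02). Adjusted over each list alone, 0 members passed in any of the 26 lists.

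**Figure D3:**
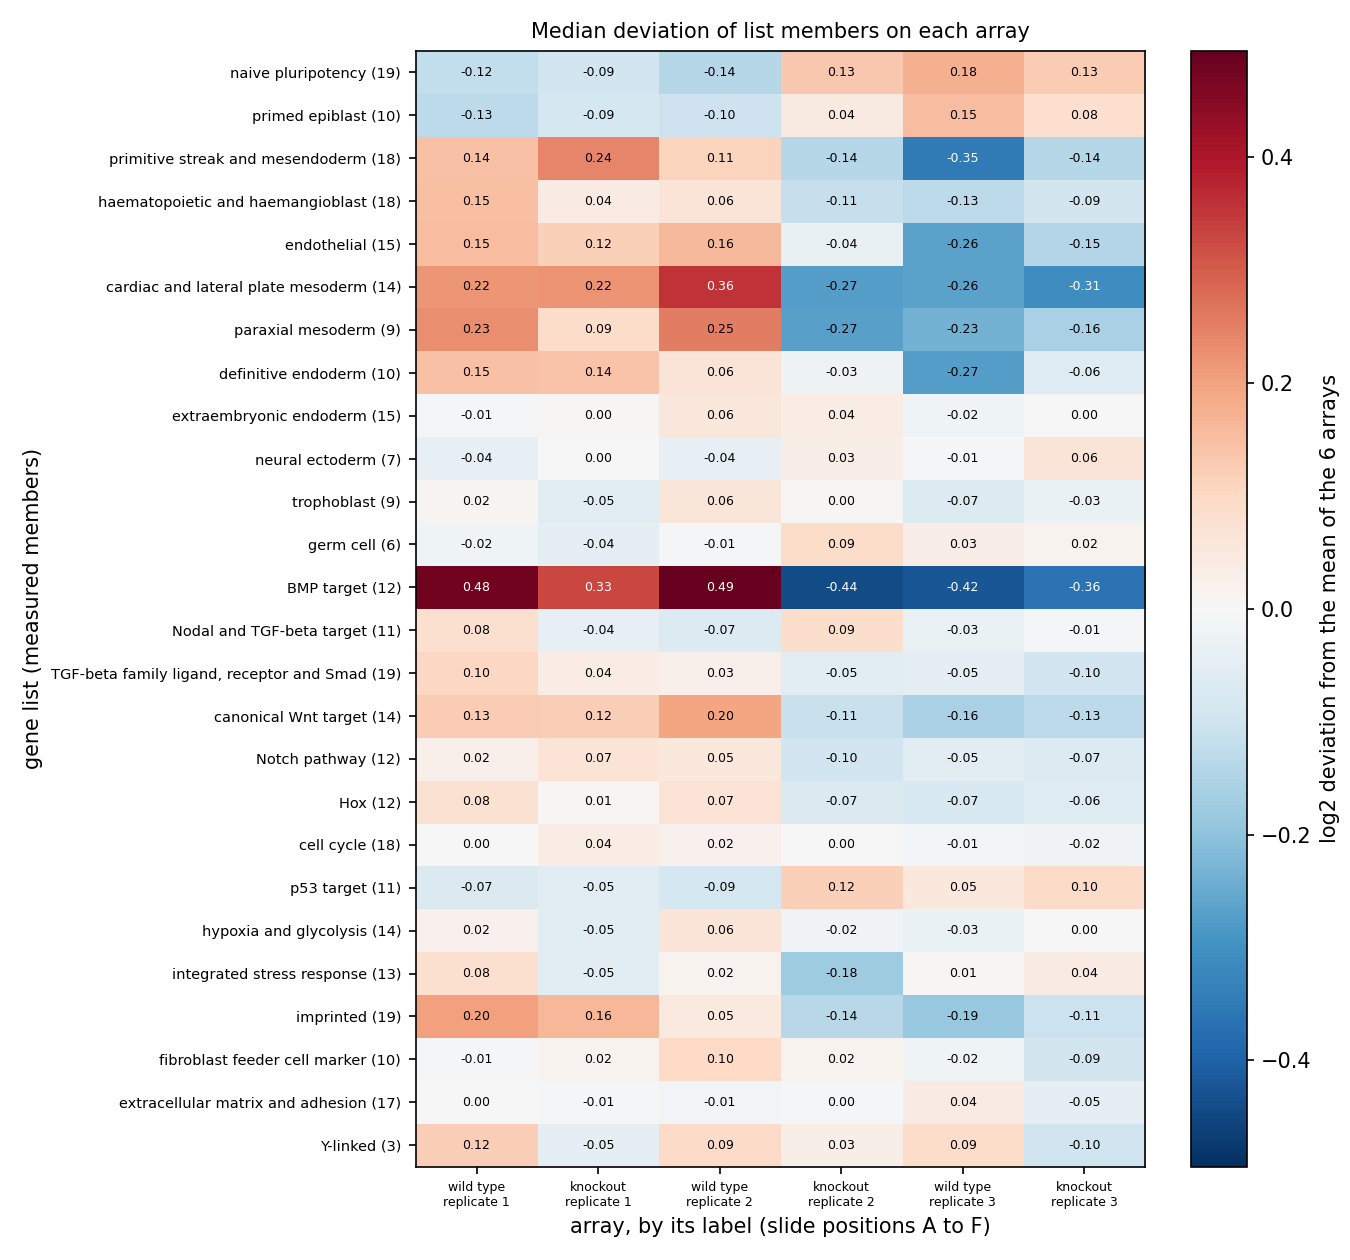
Median log2 deviation of the members of each gene list from their mean over the 6 arrays, per array in slide positions A to F, with the number of measured members in brackets. The BMP target list lay at 0.48, 0.33 and 0.49 on the first 3 arrays and at -0.44, -0.42 and -0.36 on the last 3, across the labels.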

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

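Subtraction of the background peak, cyclic loess, the further quantile step, the slide position block and the omission of 2 arrays were chosen after the data were seen. The count of called genes was 0 under every alternative run except the omission of 2 arrays, namely with no background correction, subtraction of the background peak, cyclic loess, a further quantile step, no filter, the stricter filter, every probe tested, trend and robust moderation, array weights, the replicate block, slide position as a block, a 2-fold threshold, and each array left out in turn. Without the arrays labelled knockout replicate 1 and wild type replicate 3 together, it was 1338 genes, the Eng difference was -0.675, and 15 lists passed in place of 2, the 10 named below with primed epiblast, primitive streak, TGF-beta family, imprinted and feeder fibroblast lists. Leaving out 1 array gave 0 genes throughout, an Eng difference of -0.521 to -0.145, and 0 to 10 lists. The 10 lists came without wild type replicate 3 or without knockout replicate 1, and 0 came without any of the other 4 arrays. The number of lists was 0 with the stricter filter, 0 with an estimated correlation, 0 with fry, 10 with array weights and 8 with the replicate block; the cause was not tested. The 10 lists were in each case naive pluripotency, haematopoietic, endothelial, cardiac, paraxial, BMP target, Wnt target, Notch, Hox and p53, and the replicate block gave these without Notch and Hox. With every probe tested, 3 lists passed, naive pluripotency added. The Eng difference stayed negative in all 17 alternatives that gave it, from -0.675 to -0.079, with limma adjusted p from 0.000448 to 1.00; the stricter filter removed Eng. The replicate block gave 0 genes and -0.278 for Eng. The replicate numbers were not taken as pairing the arrays, because deviations from the label means correlated at 0.61, -0.30 and 0.53 for numbers 1, 2 and 3. Of the single genes named, Uty (-0.063) turned to 0.002 with slide position as a block and to 0.011 without wild type replicate 2, with -0.193 as its lowest value without arrays. Kit (0.116) turned to -0.002 without the 2 arrays in doubt, with 0.177 as its highest value without arrays, and the cause was not tested. In all, 3 single-gene values turned, 22 passed the threshold, all without the 2 arrays in doubt, and 990 stayed on their side. The planned neqc and the median centring after it were not run, and the planned normexp with offset 50 became the main setting without its quantile step, and with that step the counts were 0 genes and 2 lists and Eng stayed at -0.278; detection p filters were replaced by the background limits. The submitters' values on the log2 scale are the setting without background correction. Low signal over background limits the dim genes, Eng among them. Six3, Kdm5d, Atf3, Spi1, Smarcd3 and Sox7 also lay below the background limit on 1 or more arrays.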

Other observations

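The tests of exchanged titles, array signals, differentiation runs and chromosomes across the array clusters, and the values without 2 arrays, were chosen only after the clusters had been seen. The genes with the widest spread over the 6 arrays, ranked without regard to label, included 15 members of lists fixed beforehand among the widest 30. Mesp1, a transcription factor of nascent mesoderm, measured 3723, 3379 and 549 on wild type replicates 1, 2 and 3 and 3105, 797 and 849 on knockout replicates 1, 2 and 3. In the same order, Pdgfra, a mesodermal growth factor receptor, measured 524, 500, 126, 491, 125 and 131, and Gata2, a blood stem cell factor, 338, 267, 61.0, 268, 71.1 and 69.2. Cxcr4, a chemokine receptor of early mesoderm and endoderm, measured 641, 589, 143, 614, 151 and 160. Igf2, an imprinted growth factor, measured 5357, 5563, 1638, 5679, 1618 and 1640. The widest gene was Hprt, a purine salvage enzyme that the E14 derivative E14TG2a lacks, at 60.5, 41.7, 2553, 53.1, 2328 and 2333, and its other 2 probes were also brighter on wild type replicate 3 and knockout replicates 2 and 3: 41.4, 37.4, 773, 39.7, 708 and 824 for one, and 37.1, 43.2, 100.1, 37.3, 106 and 111 for the other. An exception was Fbxw5, which stood out on wild type replicate 2 alone (632, against 57.4 to 75.2 on the other 5 arrays).

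Eomes, a mesendoderm factor, and Kdr, a receptor of haemangioblasts, both chosen after their values were seen, ranged from 1146 to 1382 and from 84.1 to 130 over the 6 arrays. The per-array medians of the cell cycle list lay between -0.02 and 0.04, and those of the fibroblast list between -0.09 and 0.10. Single fibroblast list members differed more, and 3 of 10 fell and 0 rose in the comparison without 2 arrays given next. With the arrays labelled knockout replicate 1 and wild type replicate 3 left out, a choice made from the values, 0 rose and 8 of 12 BMP targets fell under the knockout label, 1 rose and 10 of 14 fell in the cardiac and lateral plate list, 1 rose and 7 of 9 fell in the paraxial list, 0 rose and 6 of 18 fell in the haematopoietic list, and 8 rose and 1 of 19 fell in the naive pluripotency list.

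The arrays fell into 2 clusters that cut across the labels. The first principal component held 63.9% of the variance, with scores of -15.1, -12.4 and 13.7 for wild type replicates 1, 2 and 3 and of -13.1, 14.0 and 12.9 for knockout replicates 1, 2 and 3. The genes of chromosome 8, 685 in number, had medians of 0.04, 0.06 and -0.05 on the wild type replicates and 0.04, -0.04 and -0.05 on the knockout replicates in the same order. Of 10000 random lists of 685 genes, 0 had a median loading on that component as far from that of all genes. Chromosome 15 followed the clusters in the opposite direction, with medians of -0.028, -0.031, 0.026, -0.038, 0.033 and 0.037 in the same order. Chromosomes 11 and 17 followed them less far, chromosome 11 in the direction of chromosome 8. No random lists were drawn for chromosomes other than 8.

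For the labelled comparison, 10 of the 10 splits of the arrays into 3 and 3 gave at least as many genes as the labelled split, which gave 0. With 0 genes in the labelled split this outcome was fixed, so it decides nothing. Another split, with wild type replicates 1 and 2 and knockout replicate 1 on one side, gave 2416, which points to a structure of the samples, and 10 splits are too few for a share under 0.05. Bounds set before the comparison was seen argue against gain or loss of a whole chromosome in all cells of one line as labelled, as the autosome medians lay at most 0.039 from that of all genes, under 0.15. The feeder list median of -0.068 also met its bound, within 0.2 of 0. Each label held arrays of both clusters, so the autosome and feeder medians would both dilute a difference between the clusters. The autosome medians speak only to the labels as deposited, and the feeder median decides little. Without the 2 arrays that stood apart from their labels, 0 of 10 feeder list members rose and 3 fell. Col1a1, Col1a2 and Col3a1 lay below the background limit on all 6 arrays, which argues against many feeder cells on any array. The test for changed neighbours of Eng gave a one-sided Fisher exact p of 1, but 0 of 213 genes within 10 Mb and 0 of 12234 elsewhere were called, so it decided nothing.

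For the array clusters, a candidate explanation is that the titles or data columns of 1 knockout and 1 wild type array were exchanged: 2 arrays, 1 of each label, correlated better with arrays of the other label than with their own, but this restates the clusters and any cause of them gives the same count, so it does not support an exchange over other causes. A fault that acts on single probes is argued against by 4090 genes with 2 probes, whose loadings correlated at 0.636 against at most 0.034 in 100 shuffles. Both probes of a gene read the same labelled RNA, so this does not speak against differences in RNA quality, amplification or labelling. Gain or loss of a whole chromosome in all cells is argued against by medians of at most 0.055. The offset shrinks changes of dim genes, so such a shift would also be reduced on this scale. A change of chromosome 8 in part of the cells stays open, as 0 of 10000 random lists lay as far, but that chromosome was picked for its medians. Against 2 differentiation runs with correct labels a bound had been set and was met. It used the same fit as the slide position block above, since positions A to C and D to F are the 2 clusters. With that block 0 genes were called for the label, and 95.5% of simulated 2-fold changes, set on the corrected log2 scale, were recovered. The bound was wrongly set, because 0 genes would also be seen if endoglin loss changed no gene. The Hprt values weigh against runs of the same 2 lines, since Hprt would have had to switch within both labels (41.7 and 2553 on wild type replicates 2 and 3, 53.1 and 2328 on knockout replicates 1 and 2), but this is 1 gene, singled out as the widest of the pattern. The block count does not separate the runs from the exchange, the labels were kept as deposited, and which arrays carry knockout RNA remains open.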
